A study of Mus musculus with 6 samples.

How the data were processed

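Messenger RNA was measured in primary mouse lung alveolar epithelial type 2 cells (AEC2s), the surfactant-producing cells of the alveolus, from C57BL/6 mice. Per the labels' protocols, freshly isolated cells were grown on fibronectin-coated dishes in DMEM with 10% fetal bovine serum and infected for 48 h with a control adenovirus (Con-Ad) or an adenovirus for Slug (Slug-Ad), the zinc finger transcription factor encoded by Snai2. Total RNA was extracted with TRIzol and made into libraries with a stranded KAPA kit. The 6 libraries formed 2 groups of 3, numbered 1 to 3 in each group, and the labels give 3 mice per group.

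Per the submitters' processing notes, HISAT2, StringTie, FastQC 0.10.1 and the mouse build mm10 were used. Their roles, the annotation and the other versions are not given in the sources used here. Each deposited table holds an FPKM value (fragments mapped to a transcript, scaled by its length and by the mapped fragments of the library), computed by the authors, for each of the same 23326 protein-coding transcripts of 12344 genes. The labels name no filter, but 0 transcripts had a mean under 0.5 FPKM in both groups, so the values look limited to transcripts above that level in at least 1 group. FPKM values summed over a library to between 342314 and 357166 and carry no read counts, so depth is unknown, no counting interval or detection floor is given, and precision is taken from the spread between libraries. An FPKM of 0 is described as listed at 0. No 2 libraries held identical values. The design fixed in advance foresaw TPM, with FPKM in its place if TPM was absent, and FPKM was used. A count-based test was not run because no counts were used here.

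The FPKM values of the transcripts of each gene identifier were summed, and 1 was added before taking log2. Fold changes given as log2 are on this log2(FPKM + 1) scale, which understates the change of low genes, whereas folds written as such are ratios of group means. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested (11369 of 12344). The groups were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All gene-level p-values are two-sided, and an exact permutation test was added for Snai2. Values are given as mean ± SD over 3 libraries per group unless stated otherwise. Version 1.17.8 of data.table read the files, statmod 1.5.0 was loaded for limma, and plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

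A set of 38 gene lists covering the epithelial-mesenchymal transition, junctions, alveolar and other lung cell types, matrix, signalling pathways, stress, inflammation and metabolism was written before the data were examined. Of these, 34 had at least 3 measured members and were tested with camera, a competitive gene set test in limma, at its preset inter-gene correlation of 0.01. Camera was also run with a correlation estimated per list, where no list was called in any fit. That form judges a list against the spread of the few libraries instead of all genes, so it has little power here. Lists with an estimate below the preset lost their calls too, namely YAP/TAZ targets (−0.02), senescence (−0.05) and Wnt pathway (−0.01). A call lost there thus does not by itself show that correlation between genes had made it. Members were also counted after adjustment over the list alone. Older gene symbols were matched through a fixed list of synonyms, and Snai2 was kept out of every list. Genes named in the text follow a rule also set beforehand: Snai2 and 12 fixed marker genes, the 10 largest changes in each direction among called genes with non-overlapping groups and a higher mean of at least 5 FPKM (predicted and small RNA genes left out), and the 4 members of each list with the smallest unadjusted p. Other genes named were chosen after their values were seen, and the text says so.

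The labels give the same replicate numbers to both groups but do not say that a number marks 1 animal or day. Deviations from the group means correlated over genes at 0.32, 0.32 and 0.24 between same-numbered libraries. Between libraries of different numbers they correlated at −0.24 to −0.09. The deviations of a group sum to 0, so these negative values follow from the positive ones and are no separate contrast. All 3 same-numbered correlations lay above the bound of 0.1 set in advance for treating the numbers as pairs. The fit without a block stayed the primary one, and values with the replicate number as a block are given where they change a call or a count. In the text, a pair means the Con-Ad and the Slug-Ad library of 1 number.

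The fits were tested on simulated data with the means and spread of the 11369 genes. Of 50 genes changed by 0.5 on the log2 scale, 34% were called, rising to 78% at 1 and 100% at 2. Beside 17, 39, 50 and 50 genes called at changes of 0.5, 1, 2 and 3, 14 of 11169 unchanged genes were called. The simulation changed 200 genes, and more calls loosen the adjusted threshold. These shares may thus be too high for data with 27 calls. None of 33 unchanged lists was called in simulated data with deviations shared within pairs. Those deviations had an SD of 1 on the log2 scale for every gene and were not fitted to the data. Genes were also drawn independently there, so correlation between genes is not covered. Alternatives covered pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, median-of-ratios and quantile scaling, robust empirical Bayes, library weights, the highest transcript of a gene in place of the sum, the replicate block, leaving out each library, an estimated correlation, and fry. Rescaling all libraries to the same total and removal of each library's trend on GC content and transcript length were added after seeing the data, as were combinations of the block with that correction, with the estimated correlation and with fry, and the estimated correlation in every other alternative. Sequence properties came from GENCODE M21 (GRCm38, the assembly of mm10), which held 99.6% of the listed transcripts. Coordinates are those of the deposited tables. Isoform use was compared with diffSplice in limma and Simes p-values, also chosen after seeing the data.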

Results

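To ask how raised Slug expression alters the transcriptome of alveolar epithelial cells, RNA sequencing was carried out on mouse AEC2s 48 h after infection with control or Slug adenovirus. Each group comprised 3 libraries, and expression was given as FPKM per protein-coding transcript, summed here per gene. Total FPKM ranged from 342314 to 350461 in the Con-Ad libraries and from 348254 to 357166 in the Slug-Ad libraries, and the 10 most abundant genes took 4.77% to 5.06% of it. Cultures of both groups held transcripts of surfactant protein C (Sftpc, 690 ± 180 FPKM in Con-Ad) beside mesenchymal and matrix transcripts such as Vim (407 ± 56.8 FPKM) and Fn1 (219 ± 54.6 FPKM).

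Snai2, the gene encoding Slug, was first examined in every library. It stood at 11.1, 7.91 and 6.48 FPKM in Con-Ad replicates 1 to 3 and at 1475, 1492 and 1542 FPKM in Slug-Ad replicates 1 to 3. The group means were 8.51 ± 2.39 and 1503 ± 34.6 FPKM (SD, n = 3 each), a 177-fold difference with a log2 change of 7.33 ± 0.17 (SE, limma adjusted p = 2.0e-05). The exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 allow. Snai2 (ENSMUSG00000022676) lies on chromosome 16 at 14705852 to 14709395 in mm10, where the tables list 1 transcript, and its FPKM does not separate viral from chromosomal transcripts.

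Beyond Snai2, few genes passed the test, and most of those were higher in Slug-Ad. Chrnb1, the beta subunit of the muscle acetylcholine receptor, rose 8.23-fold from 8.65 ± 1.08 to 71.2 ± 2.05 FPKM (log2 change 2.91 ± 0.10 SE, adjusted p = 0.00012). Il13ra2, a decoy interleukin receptor, rose from 1.06 ± 0.50 to 8.88 ± 2.31 FPKM, and the membrane ubiquitin ligase gene March9 rose from 1.49 ± 0.25 to 7.22 ± 0.86 FPKM. The retromer component gene Vps26a rose (17.6 ± 1.65 to 43.5 ± 1.47 FPKM), as did the sorting receptor gene Sort1 (3.45 ± 0.48 to 10.98 ± 1.13 FPKM) and the vacuolar proton pump subunit Atp6v0e2 (1.81 ± 0.46 to 8.25 ± 1.59 FPKM). Bst2, which encodes the interferon-induced virus-tethering protein tetherin, rose 2.47-fold from 19.7 ± 1.36 to 48.7 ± 5.08 FPKM. Reep2 rose 3.78-fold, Ccdc71 2.77-fold and Pnpla2, the adipose triglyceride lipase gene, 2.21-fold.

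**Figure D1:**
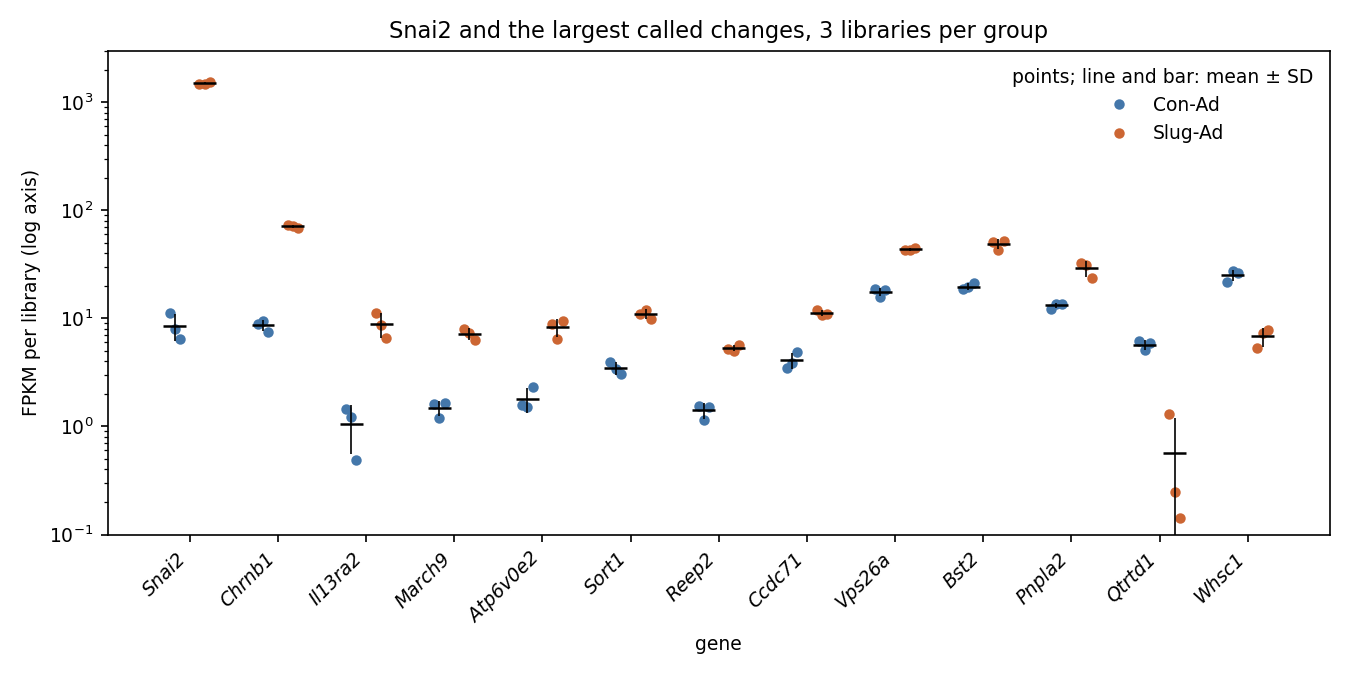
FPKM per library (log axis) of Snai2 and of the genes with the largest called changes in each direction, with 3 Con-Ad and 3 Slug-Ad points per gene, a line for the mean and a bar for the SD (the lower bar of Qtrtd1 runs off the axis). Snai2 stood at 8.51 FPKM in Con-Ad and 1503 FPKM in Slug-Ad, and the 3 points of each group do not overlap for any gene shown.

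In all, 27 of 11369 genes differed at an adjusted p under 0.05, with 25 higher and 2 lower in Slug-Ad, and 15 changed at least 2-fold, 13 of them higher. At an unadjusted p under 0.05 there were 1193 genes (697 higher, 496 lower), or 2061 with the replicate block, where 568 are expected by chance. That value takes no account of the pairs. Splitting the 6 libraries in the other ways that part all 3 pairs gave 211, 218 and 202 such genes. Splits that keep same-numbered libraries together gave 526 to 827. The 3 values of each group did not overlap for 1985 genes, or 17.5% of those tested, against 10% by chance, which also takes no account of the pairs. Among the other genes that rose, which were outside the naming rule and picked after their values were seen, were the growth factor gene Pdgfa (21.4 ± 2.45 to 40.2 ± 1.85 FPKM), the junctional adhesion molecule gene Jam2 (18.9 ± 2.08 to 39.7 ± 2.78 FPKM), the transcription factor gene Foxp1 (40.5 ± 3.60 to 74.9 ± 4.25 FPKM), Erap1, which encodes a peptide-trimming aminopeptidase of the endoplasmic reticulum, and the proton pump subunit Atp6v1f. Entpd4, Gm21685 and Gkap1, picked in the same way, also rose, but the transcripts of Entpd4 and Gm21685 share 100% of their 31-base words with other genes, and Gkap1 and Atp6v1f share 40.4% and 25.3% of theirs with other genes, so the values of these 4 genes are uncertain.

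The 2 genes that fell were Whsc1 and Qtrtd1. Whsc1, a histone methyltransferase gene on chromosome 5 (33820725 to 33897966), fell from 25.2 ± 2.94 to 6.85 ± 1.36 FPKM (log2 change −1.75 ± 0.16 SE, adjusted p = 0.019). Its transcript Whsc1-002 stood at 22.0 ± 2.45 FPKM in Con-Ad and 0.63 ± 0.37 FPKM in Slug-Ad, whereas Whsc1-004 stood at 1.92 ± 0.21 and 3.65 ± 0.41 FPKM. Whsc1-001 stood at 0.46 ± 0.18 and 1.83 ± 0.64 FPKM, and Whsc1-005 at 0.90 ± 0.11 and 0.74 ± 0.37 FPKM. Qtrtd1, a homolog of tRNA-modifying queuine transferase, had 1 listed transcript, which fell from 5.73 ± 0.59 to 0.56 ± 0.64 FPKM (adjusted p = 0.0498).

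With the replicate number as a block, 26 genes were called (19 higher, 7 lower), 16 of them shared with the 27 above. Of the genes named so far, Ccdc71 (adjusted p = 0.069 with the block), Pnpla2 (0.072), Pdgfa (0.072), Atp6v1f (0.054), Entpd4 (0.072), Gkap1 (0.072) and Qtrtd1 (0.072) lost their calls in that fit. The 10 genes that gained a call with the block were Dcn, Serpinb2, Adam15 and Odc1, which were higher, and Tagln, Acta2, Tpm2, Ctgf, Tmem204 and Il11, which were lower (block adjusted p between 0.030 and 0.036). Without the block, a filter of 5 FPKM also called Tpm2 (0.046) and Adam15 (0.045), and removal of the GC and length trend also called Tpm2 (0.035). Adam15, Odc1, Tmem204 and Il11 were named after their values were seen, and Odc1 shares 52.0% of its words with other genes.

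With the highest transcript of each gene in place of the sum, 11 of the 27 calls were lost. These included Pnpla2, whose log2 change of 1.08 went to 0.47 (adjusted p = 0.72), Foxp1, whose change went the other way from 0.87 to 2.26 (0.15), Pdgfa (0.35), Qtrtd1 (0.088), Sort1 (0.072), Gkap1 (0.057), Atp6v0e2 (0.052) and Entpd4 (0.090). Whsc1 kept its call there, and its log2 change went from −1.75 to −3.83 (0.0034). Its highest transcript is Whsc1-002, whose fall lowers the sum, so this call is no separate support for a fall of the gene. Il13ra2 missed the threshold with a pseudocount of 0.1 (0.059) and with libraries rescaled to equal totals (0.054). Qtrtd1 also missed it with a pseudocount of 0.1 (0.12, with a log2 change of −3.57 against −2.18) or 0.5 (0.070), robust empirical Bayes (0.054), library weights (0.055), rescaling (0.092) and removal of the GC and length trend (0.054). Rescaling also ended the calls of Pnpla2 (0.058), Gkap1 (0.052) and Entpd4 (0.054), and quantile normalization those of Gkap1 and Entpd4 (both 0.054). Leaving out Con-Ad replicates 1, 2 and 3 left 14, 8 and 5 calls, and leaving out Slug-Ad replicates 1, 2 and 3 left 8, 7 and 2. Snai2 and Chrnb1 were called in all 6 of these fits and Vps26a in 5, failing without Slug-Ad replicate 3 (adjusted p = 0.056), while 12 genes, Il13ra2, Atp6v0e2, Pnpla2, Erap1, Atp6v1f, Gkap1, Entpd4 and Gm21685 among them, were called in none. Qtrtd1 was called only without Slug-Ad replicate 1 (0.014), and Ccdc71 only without Con-Ad replicate 3.

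The classical transcription factors of the epithelial-mesenchymal transition did not pass the test in Slug-Ad cells. Snai1 stood at 110 ± 2.54 FPKM in Con-Ad and 121 ± 14.5 FPKM in Slug-Ad, Zeb1 at 11.04 ± 1.25 and 9.69 ± 1.19 FPKM, Zeb2 at 37.9 ± 4.39 and 32.6 ± 1.52 FPKM (higher by 0.09 on the log2 scale with its highest transcript alone), and Twist1 at 4.79 ± 1.33 and 4.61 ± 0.88 FPKM. Of the 9 measured members of the list, 0 were called over all genes. Adjusted over the list alone, 1 rose, Prrx1 (79.4 ± 2.27 to 98.0 ± 5.09 FPKM). The list as a whole had a camera adjusted p of 0.83 and a mean log2 difference of 0.01, which turned to −0.01 when libraries were rescaled to equal totals and to −0.0025 with the GC and length trend removed. The mesenchymal cadherin gene Cdh2 stood at 7.72 ± 0.83 and 7.04 ± 0.57 FPKM, Vim at 407 ± 56.8 and 444 ± 19.4 FPKM and Fn1 at 219 ± 54.6 and 187 ± 38.4 FPKM, none of them called.

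Genes of epithelial identity were lower as a group in Slug-Ad. Of 20 measured members, 19 had a lower mean and 16 were lower in all 3 pairs, with a mean log2 difference of −0.25 and a camera adjusted p of 4.1e-05 (adjusted p = 0.86 with an estimated correlation). That estimate was 0.62 against the preset 0.01. With fry the list was not called (adjusted p = 0.60, or 0.053 with the replicate block). The transcription factor gene Elf3 stood at 15.4 ± 1.42 FPKM in Con-Ad and 11.1 ± 1.72 FPKM in Slug-Ad, Rab25 at 13.1 ± 1.17 and 10.4 ± 0.69 FPKM, Tmprss2 at 7.73 ± 0.64 and 5.76 ± 1.03 FPKM, and the cell adhesion gene Epcam at 26.8 ± 4.25 and 21.8 ± 2.49 FPKM. E-cadherin (Cdh1) stood at 52.4 ± 8.63 and 40.4 ± 6.17 FPKM, lower in all 3 pairs, with a log2 difference of −0.36 (95% interval −0.73 to 0.0019, adjusted p = 0.48). No member was called over all genes. Adjusted over the list alone, 0 fell without the block and 9 fell with it.

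The junction lists leaned the same way. Among 16 tight junction genes, 12 had a lower mean, including the claudin genes Cldn4 (89.6 ± 15.6 and 62.4 ± 11.3 FPKM) and Cldn7 (26.0 ± 0.88 and 21.2 ± 2.25 FPKM), while occludin (Ocln) stood at 5.33 ± 1.38 and 5.52 ± 1.41 FPKM, turning to −0.02 on the log2 scale with its highest transcript alone. The list was called lower (camera adjusted p = 0.040, adjusted p = 0.86 with an estimated correlation), with 0 members called, also when adjusted over the list alone, where 2 fell with the replicate block. This call was lost without Con-Ad replicate 1 (adjusted p = 0.47) or Slug-Ad replicate 3 (0.23). It was also lost with no filter (0.059), a filter of 5 FPKM (0.075), quantile normalization (0.051), library weights (0.061), the highest transcript of each gene (0.052) and libraries rescaled to equal totals (0.065). Of 14 adherens junction and desmosome genes, 11 had a lower mean, among them the desmosomal plaque gene Ppl (15.2 ± 3.29 and 10.5 ± 1.69 FPKM), whereas Pkp2 (5.16 ± 0.42 and 7.08 ± 0.55 FPKM) and Nectin2 (39.3 ± 6.07 and 51.2 ± 5.87 FPKM) were higher. This list was not called (camera adjusted p = 0.12) except with the replicate block (0.032; adjusted p = 0.48 with an estimated correlation in that fit) and without Slug-Ad replicate 1 (0.034; adjusted p = 0.72 with an estimated correlation). Adjusted over the list alone, 0 members fell without the block and 2 with it, Ppl and Cdh1.

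Contractile genes, usually counted as mesenchymal, were lower in Slug-Ad. The smooth muscle and pericyte list had a mean log2 difference of −0.55, with 8 of 9 members lower in all 3 pairs and a camera adjusted p of 3.0e-05 (adjusted p = 0.32 with an estimated correlation). Tagln, which encodes an actin-bundling protein of smooth muscle, stood at 110 ± 28.6 FPKM in Con-Ad and 46.6 ± 11.8 FPKM in Slug-Ad, and smooth muscle actin (Acta2) at 113 ± 28.1 and 54.3 ± 11.3 FPKM. Over all genes both fell with the replicate block (adjusted p = 0.030 and 0.033) and missed the threshold without it (0.13 and 0.15). Myh11 stood at 2.90 ± 0.70 and 1.61 ± 0.32 FPKM and Des at 7.53 ± 0.24 and 5.74 ± 0.90 FPKM. Adjusted over the list alone, 3 members fell without the block and 8 with it.

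The mesenchymal marker list was also called lower (camera adjusted p = 0.040, adjusted p = 0.80 with an estimated correlation). It shares Acta2 and Tagln with the contractile list. Of its 23 members, 16 had a lower mean, and adjusted over the list alone 4 fell, namely Tpm2, Tagln, Acta2 and the matrix glycoprotein gene Sparc (617 ± 54.8 to 497 ± 16.5 FPKM). With the block 8 fell and 2 rose on that scale. Tpm2, a tropomyosin gene, stood at 65.7 ± 5.29 and 39.7 ± 3.56 FPKM and fell over all genes with the replicate block (adjusted p = 0.033, against 0.053 without it), as it did without the block under a filter of 5 FPKM (0.046) or with the GC and length trend removed (0.035). The list lost its call without Con-Ad replicate 3 (adjusted p = 0.30), Slug-Ad replicate 1 (0.077) or Slug-Ad replicate 2 (0.054), and with no filter (0.071).

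Targets of the mechanosensitive coactivators YAP and TAZ were called lower as a list (camera adjusted p = 0.028, adjusted p = 0.36 with an estimated correlation), with 11 of 15 members lower in mean. With the highest transcript of each gene it missed the threshold (0.052). Ctgf, a matricellular growth factor gene also named Ccn2, stood at 534 ± 135 and 355 ± 77.1 FPKM and fell with the replicate block (adjusted p = 0.033, against 0.41 without it). Amotl2 stood at 48.7 ± 5.03 and 36.9 ± 3.83 FPKM, a direction that turned with its highest transcript in place of the sum (log2 difference 1.097), and Crim1 at 23.8 ± 2.93 and 18.1 ± 2.44 FPKM, with 0 members called when adjusted over the list alone and 4 falling with the block. The TGF-beta pathway list, which shares Ctgf, was not called (camera adjusted p = 0.089) except without Slug-Ad replicate 2 (0.042) and with the highest transcript of each gene (0.034), with adjusted p = 0.61 and 0.36 in those fits with an estimated correlation. Tgfb3 fell when adjusted over the list alone (14.3 ± 1.60 to 9.43 ± 0.73 FPKM), as did 6 members with the block, where 1 rose. The list of collagens and matrix was not called either (camera adjusted p = 0.089) except without Con-Ad replicate 1 (0.022; adjusted p = 0.57 with an estimated correlation). In it the basement membrane genes Col4a1 (81.7 ± 3.69 and 67.0 ± 2.64 FPKM) and Col4a2 (59.1 ± 1.05 and 48.3 ± 3.00 FPKM) lay opposite to the proteoglycan gene Dcn (129 ± 27.9 and 220 ± 45.5 FPKM), which rose with the replicate block (adjusted p = 0.030, against 0.27 without it). Of the matrix genes, adjusted over their list alone, 0 passed without the block, and 2 rose and 5 fell with it.

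Wnt pathway genes were called lower (camera adjusted p = 0.040, adjusted p = 0.37 with an estimated correlation), with 15 of 17 lower in mean and 0 called when adjusted over the list alone (2 fell with the block), for example Wnt7a (5.25 ± 0.70 and 3.50 ± 0.60 FPKM). The Wnt call held only without Slug-Ad replicate 2 among the leave-out fits (adjusted p = 0.023; adjusted p = 0.53 with an estimated correlation), and elsewhere rose to 0.057, 0.087 and 0.053 without Con-Ad replicates 1, 2 and 3 and to 0.077 and 0.11 without Slug-Ad replicates 1 and 3. It was also lost with no filter (0.10), a filter of 5 FPKM (0.18), quantile normalization (0.051), the highest transcript of each gene (0.052) and libraries rescaled to equal totals (0.060). Notch pathway genes were not called (camera adjusted p = 0.63).

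**Figure D2:**
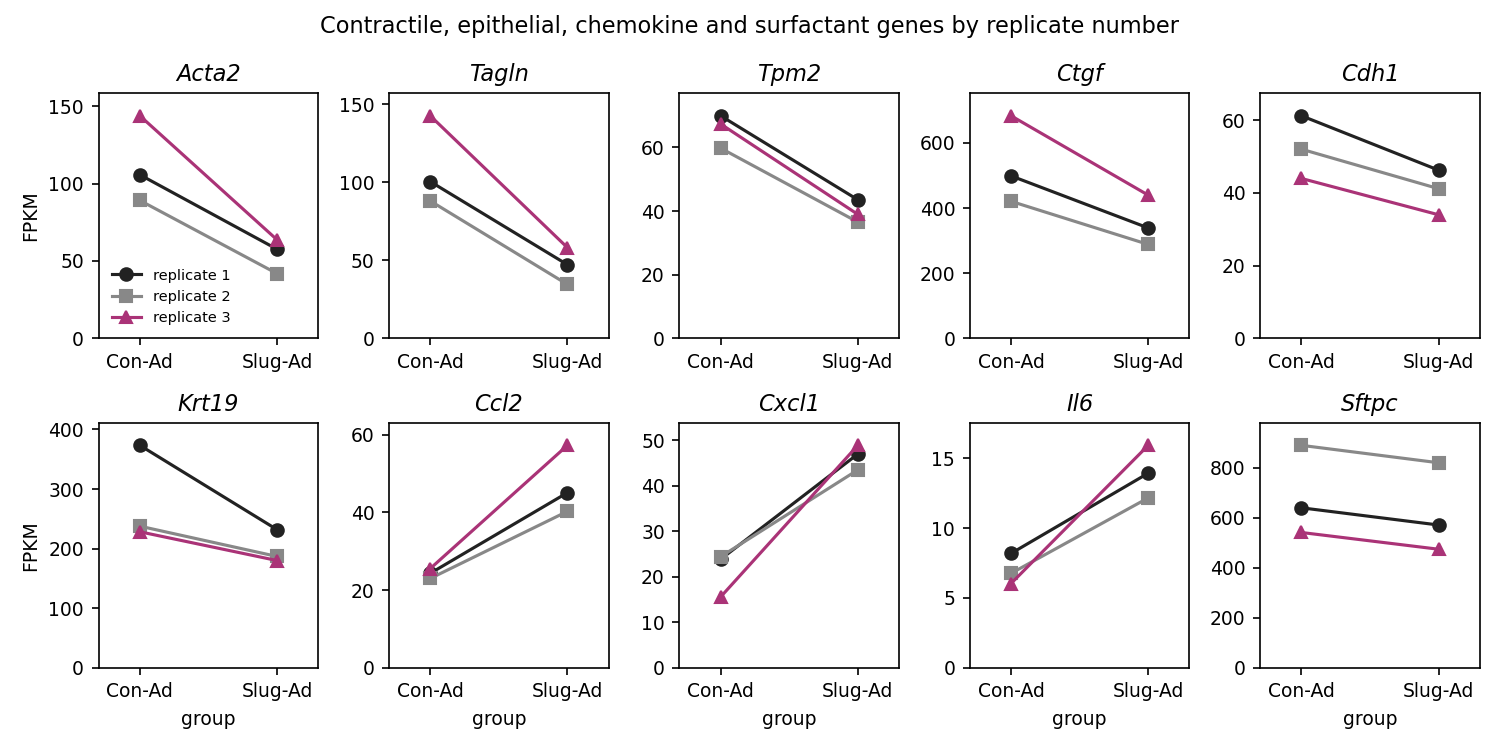
FPKM (linear axes from 0) of contractile, epithelial, chemokine and surfactant genes in Con-Ad and Slug-Ad, with a line joining the libraries of each replicate number. Acta2, Tagln, Tpm2, Ctgf, Cdh1, Krt19 and Sftpc were lower and Ccl2, Cxcl1 and Il6 higher in Slug-Ad in all 3 pairs, though none was among the 27 genes called over all genes. Acta2, Tagln, Tpm2 and Ctgf were called with the replicate block, Tpm2 also in 2 fits without it, and Ccl2 with the block and the GC and length correction together.

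Inflammatory genes of the NF-kB program gave the strongest list call. Of 19 measured members, 17 had a higher mean and 14 were higher in all 3 pairs, with a mean log2 difference of 0.46 and a camera adjusted p of 2.0e-08 (adjusted p = 0.28 with an estimated correlation). The monocyte chemokine gene Ccl2 stood at 24.3 ± 1.27 FPKM in Con-Ad and 47.5 ± 8.76 FPKM in Slug-Ad, the neutrophil chemokine gene Cxcl1 at 21.3 ± 4.95 and 46.4 ± 2.73 FPKM, the cytokine gene Il6 at 6.99 ± 1.09 and 14.0 ± 1.88 FPKM, and the acute phase gene Saa3 at 0.89 ± 0.16 and 2.29 ± 0.26 FPKM. No member passed over all genes (adjusted p = 0.066 for Ccl2), although Ccl2 rose in the fit joining the block with the GC and length correction (0.038). Adjusted over the list alone, 8 rose, or 11 with the replicate block.

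The senescence list shares Il6, Ccl2 and Cxcl1 with that list and was called higher (camera adjusted p = 0.028, adjusted p = 0.36 with an estimated correlation), with 10 of 17 members higher in mean. Its median log2 difference was 0.03 against a mean of 0.25. The stress cytokine gene Gdf15 stood at 10.3 ± 1.81 and 18.8 ± 4.66 FPKM, and 5 members rose when adjusted over the list alone (7 rose and 2 fell with the block). The interferon response list was called higher as well (camera adjusted p = 0.028, adjusted p = 0.80 with an estimated correlation), although only 4 of its 16 members were higher in all 3 pairs. Bst2 was its 1 member called over all genes, and Bst2 and Oasl1 (0.85 ± 0.49 to 2.89 ± 0.37 FPKM) rose when adjusted over the list alone, joined by Ifit1 with the block. Ifit1 stood at 0.97 ± 0.35 and 1.87 ± 0.35 FPKM and Isg15 at 3.14 ± 1.24 and 4.48 ± 0.58 FPKM. With the replicate block neither the senescence nor the interferon list was called (both adjusted p = 0.072), and the interferon call was also lost without Con-Ad replicate 3 (0.20) or Slug-Ad replicate 1 (0.077). The highest transcript of each gene ended both calls (0.052 for senescence and 0.074 for interferon), quantile normalization that of senescence (0.051) and a filter of 5 FPKM that of interferon (0.25).

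Other stress programs did not pass. The immediate early and heat shock list had a camera adjusted p of 0.089, with Junb at 136 ± 1.43 and 157 ± 3.67 FPKM and Fosb at 4.61 ± 0.83 and 6.93 ± 0.29 FPKM, a direction that turned with its highest transcript in place of the sum (log2 difference −1.097). The list was called higher without Con-Ad replicate 1 or Slug-Ad replicate 3 (both adjusted p = 0.022; adjusted p = 0.72 and 0.86 with an estimated correlation), and adjusted over the list alone 0 members rose without the block and 5 with it. The p53 target list had a camera adjusted p of 0.39 (0.029 without Con-Ad replicate 1, where the adjusted p was 0.99 with an estimated correlation), the unfolded protein response list 0.93 and the oxidative stress list 0.83, the last with Sod2 rising when adjusted over the list alone (25.7 ± 2.21 to 37.8 ± 3.29 FPKM), 1 of 3 members that did so with the block. On that scale the block also let 1 p53 target rise, 1 unfolded protein response gene rise and 1 fall, and 1 hypoxia gene fall, where 0 did without it. Hypoxia and glycolysis genes had a camera adjusted p of 0.95 with a test direction opposite to their mean difference of 0.02, which itself changed sign under quantile normalization (−0.0017), rescaling (−0.0045) and with the highest transcript of each gene (−0.15). The fibrinolysis list was not called (camera adjusted p = 0.86), and its leading members differed in direction. Serpinb2, a plasminogen activator inhibitor gene, stood at 14.7 ± 2.55 and 32.9 ± 5.42 FPKM and rose over all genes with the replicate block (adjusted p = 0.036, against 0.077 without it), whereas tissue factor (F3) fell when adjusted over the list alone (162 ± 8.0 to 114 ± 12.1 FPKM), 1 of 3 members that did so with the block.

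Cholesterol and fatty acid synthesis genes were called higher (camera adjusted p = 0.028, adjusted p = 0.94 with an estimated correlation), with 17 of 25 higher in mean and 2 rising when adjusted over the list alone. These were Srebf2, a master regulator of sterol synthesis (26.4 ± 0.57 to 36.4 ± 1.03 FPKM; adjusted p over all genes 0.060, or 0.049 with a filter of 5 FPKM), and Acly, which makes cytosolic acetyl-CoA (52.5 ± 4.47 to 71.5 ± 4.54 FPKM) and turned direction with its highest transcript in place of the sum (log2 difference −0.08). Ribosomal protein genes were also called higher (camera adjusted p = 0.028, adjusted p = 0.94 with an estimated correlation), by a mean of only 0.07 on the log2 scale, with 29 of 35 higher in mean and 0 called when adjusted over the list alone. The lipid call was lost without Con-Ad replicates 1 and 3 (adjusted p = 0.19 and 0.070) or Slug-Ad replicate 2 (0.37), and the ribosomal call without Con-Ad replicates 1 and 2 (0.43 and 0.16) or Slug-Ad replicate 3 (0.71). The ribosomal call was also lost under quantile normalization (0.23), library weights (0.054) and removal of the GC and length trend (0.096, or 0.054 with the block). Mitochondrially encoded genes (camera adjusted p = 0.26), ion and fluid transport genes (0.23) and proliferation genes (0.95) were not called. The first were called lower without Slug-Ad replicate 3 and the second without Con-Ad replicate 3 (both adjusted p = 0.046; adjusted p = 0.92 and 0.73 with an estimated correlation). The proliferation list, whose mean of −0.02 was opposite to the test's direction and turned to 0.05 with the highest transcript of each gene, was called lower without Con-Ad replicate 1 (adjusted p = 0.0022) and higher without Slug-Ad replicate 1 (0.017). Neither call held with an estimated correlation (adjusted p = 0.99 and 0.74). On the scale of the list alone 0 members passed without the block, and 1 rose and 1 fell with it.

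Markers of the alveolar lineages did not pass the test. Of 21 AEC2 markers, 15 had a lower mean and 0 were called (camera adjusted p = 0.63). Sftpc stood at 690 ± 180 and 622 ± 178 FPKM and was lower in all 3 pairs, while the lamellar body transporter gene Abca3 stood at 7.17 ± 1.13 and 9.51 ± 1.14 FPKM. AEC1 markers were not called (camera adjusted p = 0.21) except without Con-Ad replicate 3 (0.035; adjusted p = 0.71 with an estimated correlation). On the scale of that list alone 0 members fell, or 3 with the block. Ager stood at 15.3 ± 3.92 and 12.5 ± 0.80 FPKM and Lmo7 at 66.0 ± 8.99 and 50.6 ± 5.01 FPKM. Markers of the transitional state seen after alveolar damage, a list that shares 2 keratin genes with epithelial identity and Cldn4 with tight junctions, had 10 of 15 members lower in mean. That list was called lower with the replicate block (adjusted p = 0.020; 0.55 with an estimated correlation in that fit) and not without it (0.058). It was also called without Con-Ad replicate 2 (0.013), Con-Ad replicate 3 (0.025) or Slug-Ad replicate 1 (0.0042) and with the GC and length trend removed (0.034), where the adjusted p was 0.84, 0.73, 0.72 and 0.86 with an estimated correlation. Of its members, adjusted over the list alone, 0 fell without the block and 7 with it.

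Markers of other lung cells were also measured. Macrophage markers were not called (camera adjusted p = 0.71), with Cd14 at 29.6 ± 5.88 and 22.9 ± 5.37 FPKM and Chil3 at 5.25 ± 1.52 and 6.45 ± 1.72 FPKM. Fibroblast markers were not called (camera adjusted p = 0.95), with a mean of 0.03 and a median of −0.07 on the log2 scale. That mean turned to −0.03 with a filter of 5 FPKM and to −0.01 with the highest transcript of each gene. In that list Mfap4 rose when adjusted over the list alone (2.20 ± 0.11 to 4.33 ± 0.66 FPKM), and Thy1 stood at 10.3 ± 2.06 and 6.40 ± 1.33 FPKM. With the block 3 members rose and 4 fell on that scale. Endothelial (camera adjusted p = 0.26), mesothelial (0.21), club and secretory (0.62) and ciliated cell markers (0.50) were not called. The mesothelial list was called lower without Slug-Ad replicate 1 (adjusted p = 0.021; adjusted p = 0.72 with an estimated correlation). With the block, 2 mesothelial, 1 ciliated and 1 macrophage marker fell when adjusted over their own list, and 0 did without it. The remaining lists had too few measured members to test. No lymphocyte marker was measured, S100a8 was the 1 neutrophil marker (91.7 ± 49.3 and 72.3 ± 30.0 FPKM), Krt15 and Krt17 were the 2 basal cell markers, and Calca was the 1 neuroendocrine marker.

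**Figure D3:**
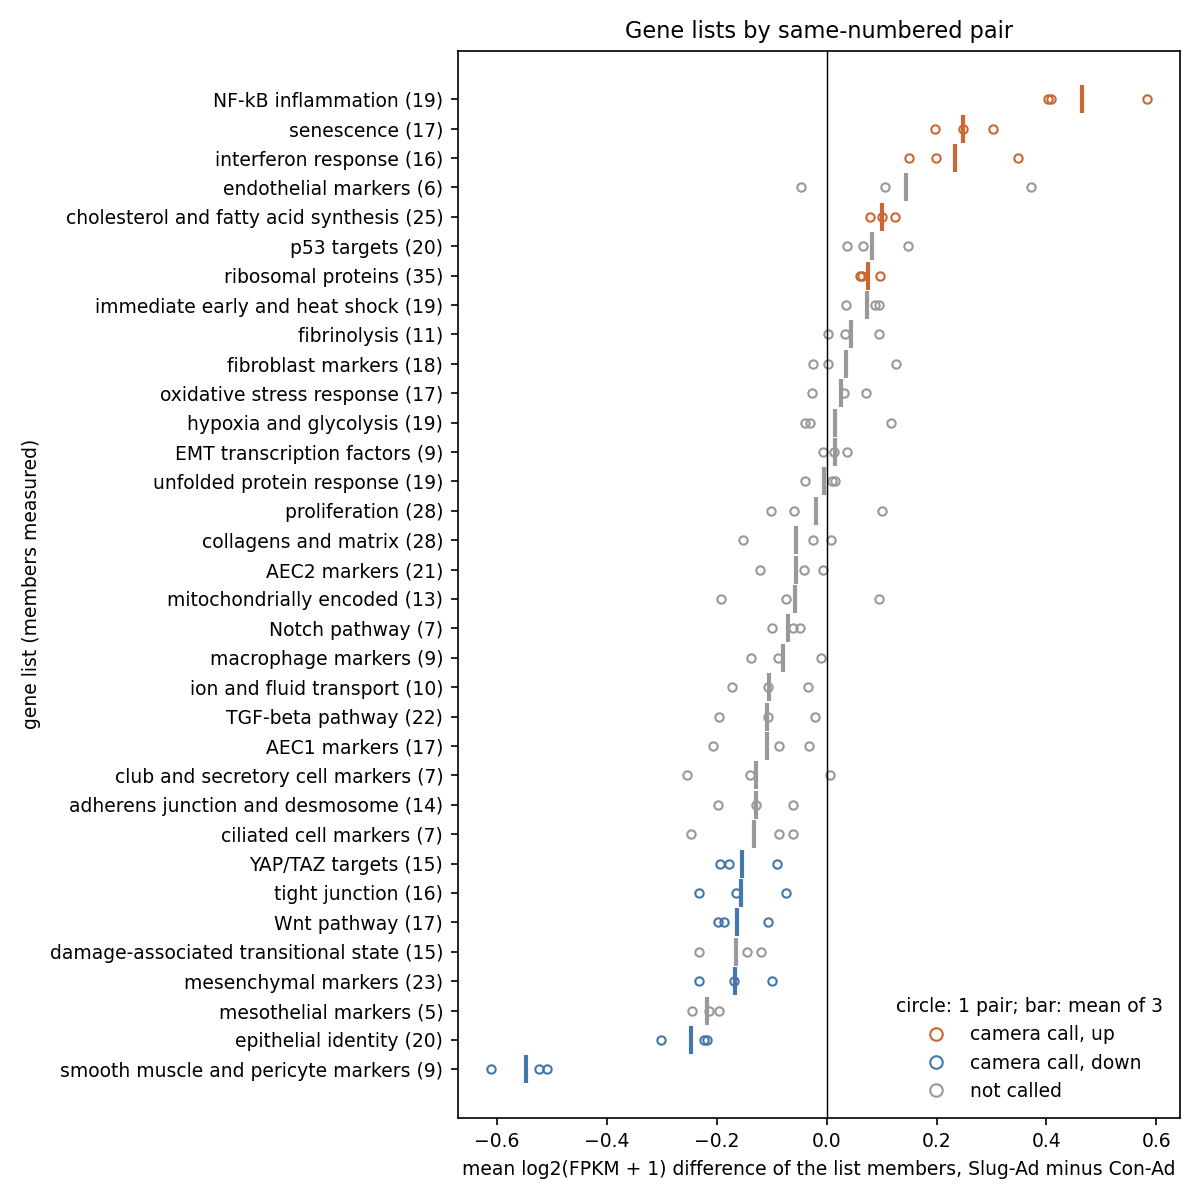
Mean log2(FPKM + 1) difference (Slug-Ad minus Con-Ad) of the measured members of each gene list, with a circle for each same-numbered pair and a bar for the mean of the 3. The NF-kB list lies highest (mean 0.46) and the smooth muscle and pericyte list lowest (−0.55), and of the 34 lists 5 were called higher and 6 lower by camera, none of which held with an estimated correlation. The estimated form has little power with so few libraries.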

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

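The fits with rescaled libraries, with GC and length correction, and with the replicate block joined to that correction, to an estimated correlation or to fry were chosen after seeing the data, as was the estimated correlation in the other alternative fits. The Snai2 change held under every alternative run (log2 7.18 to 7.53, adjusted p between 6.0e-06 and 0.0035), and so did that of Chrnb1 (2.82 to 3.03, adjusted p up to 0.0035). The number of called genes lay between 19 and 32 under every alternative that kept all 6 libraries, against 27. Without a library it lay between 2 and 14, with 2 to 13 genes higher, 0 to 3 lower and 2 to 11 changed at least 2-fold. Each of these fits has fewer libraries to estimate the spread and lacks a different library, and the cause of the fall was not tested. All fits without a library were run without the block and kept the same-numbered partner of the library left out. A deviation shared within that pair then enters the group difference, so gene and list calls lost or gained there may reflect the broken pair. Of the 27 calls, 14, 23 and 23 were lost without Con-Ad replicates 1, 2 and 3 and 22, 23 and 25 without Slug-Ad replicates 1, 2 and 3, none with a change of sign. The 2 genes lower became 1 with a pseudocount of 0.1 or 0.5, robust empirical Bayes, library weights or rescaling, 3 with the highest transcript of each gene, 4 with a filter of 5 FPKM, and 7 with the replicate block, with or without the GC and length correction; the cause was not tested. The 11 lists called became 7 under quantile normalization or with the highest transcript of each gene, 4 with fry, and 0 with an estimated correlation (10 to 12 without a library at the preset correlation). The 4 with fry were the NF-kB, smooth muscle and pericyte, YAP/TAZ and senescence lists. In every other alternative fit an estimated correlation also left 0 lists (lowest adjusted p 0.13). That form has little power with so few libraries. With the replicate block 11 lists were called by camera, 0 with an estimated correlation and 1 with fry, the smooth muscle and pericyte list. The proliferation mean of −0.02 turned to 0.21 without Slug-Ad replicate 1 (range −0.31 to 0.21 over the left-out libraries). Besides the calls named with the block above, the pairing also ended those of Rab3ip, Creld1, 2510039O18Rik and Zdhhc2, genes named after their values were seen, and changed no other. Over 166 genes followed and their 3122 comparisons with an alternative, 182 lost a call, 25 gained it and 34 of uncalled genes changed sign; over the 34 lists, 82 of 747 lost a call, 20 gained it and 38 of lists uncalled with all libraries changed sign, 1 of these a reversal (proliferation without Slug-Ad replicate 1). Robust empirical Bayes does not enter camera, and the count-based alternative was not run because no counts were used. Depth is unknown, so how far it limits low genes cannot be stated.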

Other observations

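The tests of scaling, macrophage content, antiviral response and cell makeup, and that of isoform use, were chosen after seeing the data; the tests of GC content, low expression and other splits of the libraries were set out before their results were seen.

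Some genes were called for a difference between their transcripts, a comparison that the gene sums leave out. Among 3856 genes with at least 2 transcripts past the filter, 51 were called for isoform use (limma diffSplice, Simes adjusted p under 0.05). With the replicate block 29 were called, and 27 in both fits. At an unadjusted p under 0.05 there were 384 genes where 193 are expected by chance, a value that takes no account of the pairs. The focal adhesion gene Zyx led them, with its transcript Zyx-007 at 70.6 FPKM in Con-Ad and 1.98 FPKM in Slug-Ad while Zyx-001 stood at 11.4 and 27.9 FPKM (adjusted p = 3.7e-12). Whsc1 came next (adjusted p = 6.2e-08), followed by Lpin3, Pkig and Slc7a2. All of these but Whsc1 were picked after their values were seen. The isoform test pools the spread of a gene's transcripts as if they varied independently, so its p-values rest on more than the 6 libraries. Tested alone with limma, the transcript Zyx-007 had an adjusted p of 0.0032 and Whsc1-002 of 0.0072. In Il13ra2, the transcript Il13ra2-201 was listed at 0 in all Con-Ad libraries and averaged 6.88 FPKM in Slug-Ad. Of the 10 ways to split the 6 libraries into 3 and 3, 2 gave at least as many such genes, the real split with 51 and another with 53, and 10 splits are too few for a share under 0.05. The other splits gave between 22 and 53, and those that part all 3 same-numbered pairs at most 44. The number of genes called thus does not set the real grouping apart, and the small p-values of single genes come from the same test. In simulated data, 61 of 100 genes with 1 transcript shifted by 2 on the log2 scale were recovered, with 14 unchanged genes called. That is a larger share of false calls than the threshold of 0.05 stands for. Transcripts were drawn independently there, so dependence between transcripts of a gene is not covered. The 51 calls may thus hold more false ones than the threshold states.

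Too few splits exist to test the other counts against chance, since the real one is 1 of 10. It gave 27 called genes against 4 in the highest of the others, and 2 in the highest of the other splits that part all 3 pairs; 1 split, the real one, gave as many. For gene lists, 4 of the 10 splits gave at least as many as the real 11, the highest 16, whereas the other splits that part all 3 pairs gave at most 4. The splits with more lists keep same-numbered libraries together, which reflects the same correlation between those libraries and is no further evidence for pairs.

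The first pattern weighed was that 25 of 27 called genes were higher in Slug-Ad, an imbalance that was smaller with the replicate block (73.1% higher), without Slug-Ad replicate 1 (62.5%) and at an unadjusted p under 0.05 (697 of 1193). The share of higher calls was at least 92% under median-of-ratios, quantile and rescaled values in the fit without the block. The median log2 change over all genes was −0.0037 before these scalings and −0.0029, −0.0093 and −0.025 after them. Shifts this small could hardly have turned the calls, so the share by itself does not decide on library scaling. Removing each library's trend on GC content and transcript length left 24 of the 25 called higher, and 14 with the replicate block, where 15 were called before the correction. Among genes of at least 5 FPKM in 3 libraries 87.5% of calls were higher (28 higher and 4 lower). Genes low in Con-Ad, such as Il13ra2 and March9, passed that filter through their Slug-Ad values alone. The share therefore does not decide on low power at low expression. An effect of Slug stays open and was not tested apart from the group difference.

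The second pattern was the higher NF-kB list, with a mean difference of 0.46 over the 3 pairs (SE 0.06). Macrophages carried into the cultures would bring their own markers, whose mean difference over the pairs plus 2 SE reached −0.0051 (9 of 20 markers measured). Of these Cd14 was lower and Chil3 higher in Slug-Ad in all 3 pairs. The markers were low (median of their means 2.28 FPKM in Con-Ad and 1.89 FPKM in Slug-Ad). They bear on the number of macrophages and not on how strongly those express NF-kB genes. A stronger antiviral response in the Slug-Ad dishes cannot be told apart from an effect of Slug, since viral dose is not given in the sources used here. The interferon list was called higher, but not with the replicate block (adjusted p = 0.072) or an estimated correlation (0.80), and 4 of its 16 members were higher in all 3 pairs, while its member Bst2 rose in both fits over all genes. An effect of Slug on these genes stays open and was not tested apart from the group difference.

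The third pattern was that epithelial and contractile lists were lower together. Fewer epithelial cells in the Slug-Ad dishes would raise the markers of cell types outside the pattern, but the 33 macrophage, endothelial and fibroblast markers went both ways, with a mean difference of 0.0235 (2 SE either side −0.083 to 0.13), so this stays open for the epithelial part. For the contractile part, fewer smooth muscle cells and fibroblasts together would lower fibroblast markers as much. Their mean difference over the pairs minus 2 SE was −0.059, above the contractile value of −0.55. Of the 18 fibroblast markers, however, 12 were lower and 6 higher in mean, with 8 lower and 3 higher in all 3 pairs. Their mean thus averages markers that moved apart, and a smaller loss of fibroblasts stays open. A loss of smooth muscle cells alone stays open for the contractile part only, as it would not lower epithelial genes. An effect of Slug on either list stays open and was not tested apart from the group difference.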
